A study of Mus musculus with 59 samples.

How the data were processed

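RNA sequencing values of 59 mouse libraries were used: 16 from spinal cord, 23 from glia and 20 from neurons of sandwich co-cultures. Groups were taken from the sample labels: genotype, age and sex for spinal cord, and the genotype of each partner, the cell read and the day for cultures. Per the labels, RNA was extracted with Trizol and RNeasy columns, libraries were prepared from total RNA with a standard Illumina or a Nextera kit (which of them for each library is not given), and the submitters' processing notes name Bowtie and the mm9 genome. Whether replicates are separate cultures or animals is not stated for the cultures, so they may be technical, and p-values measure only the spread between these samples. No 2 libraries of a group were copies of one another, since the spread between replicates was 13.7 to 106 times that of counting noise per gene (27 groups).

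The deposited culture values are RPKM (reads scaled by gene length and library) for 27389 entries. For 99.65% of the 22784 entries above 0 the values of a library came out as whole reads when divided by 1 common factor per library, and 80 entries were not recovered. The factor was not proportional to the reads on genes in the day 3 replicate 1 libraries. The deposited spinal cord values, for 36814 entries, are in another unit, not stated in full: reads divided by the deposited gene length and by a total for the library, on the scale of RPKM, from which a whole number of reads had been subtracted for part of the genes, so that 898 entries had a value below 0 in some library. What was subtracted is not given in the sources used here. Negative values were set to 0. Culture entries were named by Entrez ID (18854) or alias (737), and 7798 without a current symbol kept the deposited name. Spinal cord entries were named by Ensembl ID (31841) or as in the file (4973). Among the culture entries 401 symbols label more than 1 entry. Chromosomes and positions (mm9) are those deposited with the spinal cord values, matched to culture genes by symbol, and a later mouse annotation was used for gene types only.

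Reads on genes were 9.71 to 49.2 M per spinal cord library, 2.69 to 18.9 M per glial library and 5.62 to 26.6 M per neuronal library. Libraries were simulated with the gene means and spread of the real ones after median-of-ratios rescaling. In them a log2 change of 1 was found in 84% of genes at 17 weeks in spinal cord, in 79% for glia with wild-type neurons and in 70% for neurons with mutant glia, and one of 2 in 99%, 97% and 97%. In the blocked and rescaled model the rates for glia and neurons came to 92% and 90% for a change of 1. The changes were set in 200 genes drawn above a minimum mean value. Rates may be lower for genes with lower values, or where fewer genes change. The simulated values lacked the scaling differences of the deposited ones, such as those of day 3 replicate 1. The rates of the unblocked culture models may thus be too high for the deposited values. Calls among genes without a simulated change made up 0% to 6.34% of calls.

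The comparisons, tests, gene lists, rule for naming genes and most alternatives were set before the data were examined, with 1 test for each unit the values might have. Since no counts were given, DESeq2 and edgeR were not used. Values were taken as deposited, as log2(value + 1), with genes at 1 or more in at least 2 libraries of the model, and fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The spinal cord model held genotype-by-age means and sex for 16 libraries (14645 genes). Glia (14611 genes) and neurons (15065 genes) had models of their own with a mean for each pairing and day, and contrasts were averaged over days 3, 7 and 14. Neurons were compared with glia in a model of all 43 culture libraries (15867 genes). Groups with 1 library were assumed to vary like the others.

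The labels number culture replicates without saying whether equal numbers within a day belong together. After both models' calls had been seen, this was read from the correlation of residuals between different pairings of the same day and replicate number. It was above 0.1 in 15 of 15 pairs of glial libraries (median 0.72) and in 6 of 7 pairs of neuronal libraries (median 0.57, lowest 0.07), against medians of 0.02 and 0.11 across days. The rule set for this asked for every pair, so the neuronal reading fails it by 1 pair, and mutant neurons with wild-type glia, with 1 library a day, could not be checked. The second model, chosen after seeing the data, added replicate number within each day as a block in cultures, neurons included, and rescaled all values by median-of-ratios factors. Its calls were known before the correlations were read. Comparisons of day 14 with day 3 were read from the model without a block, since the block is nested in day. In spinal cord the second model was rescaled only, since replicate 1 was the female and replicate 2 the male of each group.

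There were 41 gene lists (16 of cell type markers, 25 of pathways and processes), and lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. Adjustment was over the lists of 1 comparison. Of 735 list tests 235 passed with the preset and 37 with an estimated correlation, and in the second model, day comparisons included, 217 and 51 of 734. Set overlaps were tested with Fisher's exact test among genes tested in both.

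Genes are named by rule: mouse Sod1 in each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 and the same direction in every age and sex pair or on each day, and up to 4 called members of each list with the smallest adjusted p. Where a list passed with no called member, the 2 members with the largest change are given as values. Not every gene the rule allows is printed, and 5 are not reported here and are left out of the counts of single genes across alternatives. Ctsc and the other genes shown for the overlap of glia with spinal cord were picked after their values were seen, as were the per-day values of Eif2s3y and the per-library values of Aoc3.

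Alternatives tried were median-of-ratios rescaling, no filter on low values, a pseudocount of 0.1, no sex term, an additive model of pairing and day, replicate number as a block, and leaving out each library. Chosen after seeing the data were the block within each day, that block with rescaling, limma-voom on the recovered reads, models without the day 3 replicate 1 libraries or the 17-week females, contrasts averaged over both partners, and genotype-by-day and genotype-by-sex tests. Up to 100 other splits of the libraries were refitted for each comparison. Chromosome medians were taken over genes with a mean value of at least 2, and this step was tested on simulated data, where a shift of 0.4 on chromosome 5 came out as 0.35. Figures and file handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the comparisons.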

Results

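RNA was sequenced from spinal cord and from cultured cells of mice carrying mutant human SOD1, a transgene that causes a motor neuron disease used to model amyotrophic lateral sclerosis (ALS), and of wild-type mice. The spinal cord set held 16 libraries, with 1 female and 1 male of each genotype at 4, 8, 12 and 17 weeks. The culture set held 43 libraries from sandwich co-cultures, in which glia and neurons were grown as partners and the RNA of 1 partner was read. Of these, 23 came from glia and 20 from neurons, at 3, 7 and 14 days, in each pairing of mutant and wild-type partners. Each pairing and day had 2 libraries, except 5 with 1 library: wild-type glia with mutant neurons at day 3, wild-type neurons with wild-type glia at day 3, and mutant neurons with wild-type glia at each of the 3 days.

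The values held 9.71 to 49.2 M reads on genes per spinal cord library (median 31.7 M), 2.69 to 18.9 M per glial library (median 13.6 M) and 5.62 to 26.6 M per neuronal library (median 10.9 M). Between 12607 and 13897 genes had a value of at least 1 in a spinal cord library. The 7 culture libraries numbered replicate 1 at day 3 had larger summed values than the others of their kind, with scaling factors of 1.53 to 2.23 in 3 glial libraries against 0.869 to 0.945 in the others, and of 1.46 to 1.70 in 4 neuronal libraries against 0.812 to 0.980. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. The SE beside a fold or a log2 change is always that of the log2 change.

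Mouse Sod1, the counterpart of the human transgene, was compared first in each data set. In spinal cord its values at 17 weeks were 67.7 ± 28.0 in mutants and 75.5 ± 2.35 in wild types (SD, n = 2 each), a log2 change of -0.22 (SE 0.30, adjusted p = 0.772). Over all ages the change was -0.17 (SE 0.15, adjusted p = 0.735). Since the transgene is human, mouse Sod1 checks the genotype labels only in part.

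The first question was when mutant spinal cord starts to differ from wild type. At 4 weeks the 13 genes past the threshold (6 higher, 7 lower) were 4 protein-coding genes, 5 pseudogenes, 2 small or ribosomal RNAs and 2 others. Rps19, a ribosomal protein with many pseudogene copies, rose from 0.417 ± 0.128 to 9.49 ± 0.302 (SD, n = 2 each; log2 2.89, SE 0.35, adjusted p = 0.00204). The ferritin light chain Ftl1 rose by log2 1.33 (SE 0.23, adjusted p = 0.0275), while its pseudogene Ftl2-ps was listed at 0 in the mutants. The noncoding RNA Pantr1 fell by 1.42 on the log2 scale (SE 0.20, adjusted p = 0.00484). Reads of Rps19, Ftl1 and the pseudogenes may be shared with their copies, which was not tested, so the origin of these reads is uncertain. None of the 13 passed after rescaling by median-of-ratios factors or with voom on recovered reads, where 0 genes passed in each case (limma, 700 genes at an unadjusted p under 0.05 after rescaling). The count was 126 without the first wild-type library of that age, the female.

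At 4 weeks red blood cell markers had the highest list test, with no member past the threshold over all genes and 3 of 4 adjusted over the list alone. Hba-a2 and Hbb-bt, globin chains, had log2 changes of 1.74 (adjusted p = 0.633) and 1.67 (adjusted p = 0.459). The 2 mutant libraries differed widely, at 63.6 ± 57.6 for Hba-a2 and 188 ± 164 for Hbb-bt, against 14.0 ± 1.28 and 46.5 ± 9.475 in wild types (SD, n = 2 each). This list passed with the preset correlation (adjusted p = 2.32e-09) and not with an estimated one (adjusted p = 0.12 with an estimated correlation). The endothelial, antigen presentation and oxidative stress lists passed at this age with the preset correlation alone (adjusted p = 0.992, 0.297 and 0.808 with an estimated correlation).

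At 8 weeks 35 genes passed (18 higher, 17 lower), 12 of them protein coding and 13 pseudogenes. S100a11, a calcium-binding protein, rose from 0.990 ± 0.499 to 6.06 ± 0.908 (SD, n = 2 each; log2 1.84, SE 0.32, adjusted p = 0.023). Sox2, a transcription factor of neural progenitors and glia, fell from 17.1 ± 0.816 to 9.34 ± 0.337 (log2 -0.81, SE 0.16, adjusted p = 0.0493). Aoc3, a vascular amine oxidase, fell from 2.93 ± 0.0319 to 0.0221 ± 0.0264 (log2 -1.95, SE 0.37, adjusted p = 0.0352). The interferon response, reactive astrocyte and axon injury lists had positive tests that were lost with an estimated correlation (adjusted p = 0.755, 0.755 and 0.766 with an estimated correlation). Their largest members were Ifi27l2a at log2 1.30 (adjusted p = 0.122), the metalloprotease inhibitor Timp1 at 0.58 and the injury-induced Sprr1a at 1.07 (adjusted p = 0.128). With voom on recovered reads more than 35 genes passed. After rescaling 13 genes passed, while S100a11 (log2 1.81, SE 0.41, adjusted p = 0.12), Aoc3 (-1.85, SE 0.41, 0.12) and Sox2 (-0.79, SE 0.15, 0.086) had like changes that did not pass, and no filter on low values left 1 gene. The count was 2 without the male wild-type library.

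At 12 weeks mutant spinal cord showed a broad rise of microglial and astrocytic genes. Cst7, a protease inhibitor of activated microglia, rose 9.74-fold (log2 3.28, SE 0.24, adjusted p = 8.82e-07), from 0.0389 ± 0.0550 to 9.11 ± 0.0120 (SD, n = 2 each). The chemokine Ccl3 rose 8.89-fold (SE 0.21, adjusted p = 5.5e-07) and the receptor Clec7a 8.63-fold. Serpina3n, a protease inhibitor of reactive astrocytes, rose 4.52-fold (SE 0.18, adjusted p = 2.93e-06), from 29.5 ± 2.89 to 137 ± 11.3. The intermediate filament Gfap rose 2.51-fold (SE 0.18, adjusted p = 0.000309), from 372 ± 15.8 to 938 ± 72.0.

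In the reactive astrocyte list 10 of 11 members rose at 12 weeks (10 adjusted over the list alone; adjusted p = 0.00235 with an estimated correlation), among them Timp1 5.11-fold, Vim by log2 1.92 and the cytokine receptor Osmr 2.82-fold. Of the disease-associated microglia list 11 of 17 members rose (14 adjusted over the list alone; adjusted p = 0.0046), with the receptor Trem2 at 2.79-fold. The complement list had 5 of 9 members up (7 adjusted over the list alone; adjusted p = 0.00686), led by C1qc at 4.09-fold and C1qb at 3.66-fold. Interferon-induced genes rose in 9 of 11 members (11 adjusted over the list alone; adjusted p = 0.00321), with Oasl2 at 4.15-fold, Bst2 at 3.77-fold and Ifit3 at 3.59-fold. Antigen presentation had 4 of 9 up (7 adjusted over the list alone; adjusted p = 0.00235), with B2m at 2.83-fold and H2-K1 at 3.64-fold, and the inflammatory cytokine list had 3 of 9 up (7 adjusted over the list alone; adjusted p = 0.00297), with Cxcl10 at 5.30-fold. The microglia marker list rose with these lists, with 8 of 14 members up and a median log2 change of 0.89 (adjusted p = 0.00686), and 8 of 15 lysosomal genes were up (adjusted p = 0.0298), with Lyz2 at 6.46-fold.

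Genes that fell at 12 weeks were few. Apln, a vascular peptide hormone, fell from 22.2 ± 0.987 to 11.4 ± 2.60 (SD, n = 2 each; log2 -0.92, adjusted p = 0.0123), and Arc, a neuronal activity-induced gene, fell by 0.74 on the log2 scale (adjusted p = 0.0182). Chodl, a marker of fast motor neurons, had a log2 change of -0.76 (SE 0.19, adjusted p = 0.0569), and the neurofilament Nefh had -0.70 (adjusted p = 0.138), and both passed after rescaling (adjusted p = 0.0431 and 0.0268). The motor neuron list passed for no member (1 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), as did the endothelial list, which was lower with the preset correlation (adjusted p = 0.248 with an estimated correlation). In all, 256 genes passed at 12 weeks (244 higher, 12 lower), and 231 of the 244 were protein coding. The count was 458 after rescaling (90.8% higher) and 650 with voom, and it was 102 without the male wild-type library and 137 without the female mutant. Stmn1, a microtubule regulator, had the largest rise, 11.4-fold (SE 0.73, adjusted p = 0.0148), which did not pass after rescaling (log2 3.46 against 3.51, adjusted p = 0.096).

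Microglial genes rose at 17 weeks as well. Cst7 rose 28.7-fold (log2 4.84, SE 0.24, adjusted p = 1.85e-09), from 0.0587 ± 0.0532 to 30.3 ± 10.8 (SD, n = 2 each). The lysozyme Lyz2 rose 19.9-fold (SE 0.26), from 4.29 ± 0.00831 to 105 ± 17.1, the Fc receptor-like Fcrls 16.7-fold (SE 0.36) and Clec7a 13.4-fold (SE 0.25). The disease-associated microglia list had 16 of 17 members up (16 adjusted over the list alone; median log2 1.89; adjusted p = 0.00282 with an estimated correlation), among them Tyrobp, an adaptor of Trem2, at 8.75-fold. The microglia markers moved with it, with 13 of 14 up (13 adjusted over the list alone; median log2 1.62; adjusted p = 0.00299), and the homeostatic microglia list had 5 of 8 up (6 adjusted over the list alone; adjusted p = 0.0403), with Cx3cr1 at 2.94-fold and Tmem119 at 1.98-fold. All 9 measured complement genes rose (adjusted p = 0.00299), with C1qa at 7.23-fold, C1qb at 7.53-fold and C1qc at 8.13-fold. Lysosomal genes rose in 11 of 15 members (13 adjusted over the list alone; adjusted p = 0.0167), with Cd68 at 11.4-fold, the protease Ctsd at 5.23-fold and the progranulin gene Grn at 5.19-fold.

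**Figure D1:**
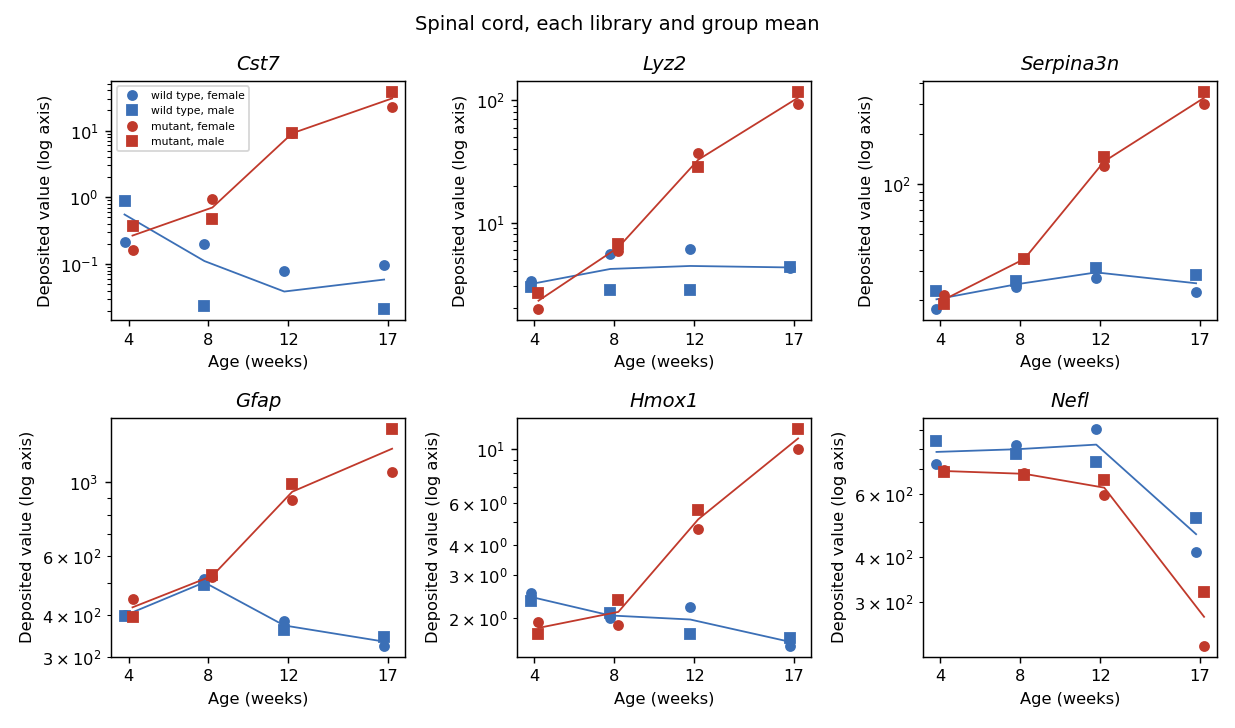
Deposited values of Cst7, Lyz2, Serpina3n, Gfap, Hmox1 and Nefl by age in weeks (log axis), with 1 point per spinal cord library, colour for genotype, shape for sex, lines through group means and values of 0 not drawn. Cst7 reached 30.3 ± 10.8 (SD, n = 2) in 17-week mutants against 0.0587 ± 0.0532 in wild types.

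Astrocytic genes rose in the same mutants. Serpina3n rose 12.5-fold at 17 weeks (log2 3.65, SE 0.18, adjusted p = 1.85e-09), from 25.4 ± 4.28 to 328 ± 39.7 (SD, n = 2 each), and Gfap 3.74-fold (SE 0.18, adjusted p = 2.02e-06), from 333 ± 13.9 to 1262 ± 266. The reactive astrocyte list had 10 of 11 members up (11 adjusted over the list alone; median log2 2.11; adjusted p = 0.00282 with an estimated correlation). The neurotoxic-type astrocyte list had 6 of 11 up (8 adjusted over the list alone; adjusted p = 0.00282), with Gbp2 at 2.77-fold, Psmb8 at 2.73-fold and Serping1 at 3.95-fold. Of 12 astrocyte markers 4 rose (4 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with the water channel Aqp4 at 2.25-fold and Aldh1l1 at 1.84-fold. Of the astrocyte glutamate and potassium handling genes 1 of 9 rose (adjusted p = 0.404 with an estimated correlation).

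Members of immune and stress lists rose as well at 17 weeks. Interferon-induced genes rose in 7 of 11 members (11 adjusted over the list alone; adjusted p = 0.0167 with an estimated correlation), with Bst2 at 3.12-fold and Ifit3 at 2.79-fold. Antigen presentation had 4 of 9 up (8 adjusted over the list alone; adjusted p = 0.00282), with B2m at 3.00-fold and Cd74, the invariant chain, at 3.52-fold. The cytokine list had 6 of 9 up (9 adjusted over the list alone; adjusted p = 0.00282), with Ccl3 at 5.72-fold, Ccl4 at 4.48-fold and Cxcl10 at 5.35-fold. TGF-beta signalling had 5 of 14 up (7 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), with Tgfb1 at 2.76-fold, and the extracellular matrix list 4 of 11 (6 adjusted over the list alone; adjusted p = 0.0898), with Fn1 at 4.18-fold. The axon injury list had 3 of 11 up (5 up and 1 down adjusted over the list alone; adjusted p = 0.183), with Sprr1a at 5.71-fold and the transcription factor Atf3 at 4.15-fold. The small heat shock protein Hspb1 rose 6.36-fold and heme oxygenase Hmox1 4.66-fold, each the only called member of its list. The heat shock list had a median log2 change of -0.10, a mean of 0.08 and a test pointing up (adjusted p = 0.354), and the oxidative stress list was lost with an estimated correlation (adjusted p = 0.211).

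Chodl and the neurofilament genes were lower at 17 weeks, in lists that did not pass with an estimated correlation. Chodl fell 3.36-fold (log2 -1.75, SE 0.19, adjusted p = 1.11e-05), from 6.95 ± 2.01 to 1.33 ± 0.00900 (SD, n = 2 each), the 1 called member of 8 motor neuron markers (adjusted p = 0.169 with an estimated correlation). The neurofilament subunits fell by 0.93 (Nefh, SE 0.21, adjusted p = 0.0124), 0.81 (Nefm, adjusted p = 0.0343) and 0.77 (Nefl, adjusted p = 0.0243) on the log2 scale, and Nefl went from 463 ± 72.0 to 273 ± 65.6. The axon and pan-neuronal lists each had 3 members down (5 adjusted over the list alone in each), with adjusted p = 0.36 and 0.302 with an estimated correlation. Sqle, a sterol synthesis enzyme, fell by 0.67 (adjusted p = 0.0414), and the cholesterol synthesis list had 2 of 16 members down, 12 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Without the filter on low values Nefh (adjusted p = 0.075), Nefm (0.21) and Nefl (0.22) did not pass, their log2 changes being the same, while after rescaling all 3 passed (adjusted p = 0.0035, 0.013 and 0.0049).

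The synapse (16 genes), oxidative phosphorylation (12), myelin (11) and ALS gene (15) lists held no gene past the threshold at 17 weeks, with adjusted p = 0.563, 0.386, 0.584 and 0.794 with an estimated correlation. In all, 661 genes passed (598 higher, 63 lower). After rescaling 1784 passed, 75% of them higher against 90.5% with values as deposited, and voom gave 1612. The 17-week females held 9.71 M (mutant) and 21.6 M (wild type) reads on genes, with scaling factors of 0.65 and 0.73, the lowest of the set.

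**Figure D2:**
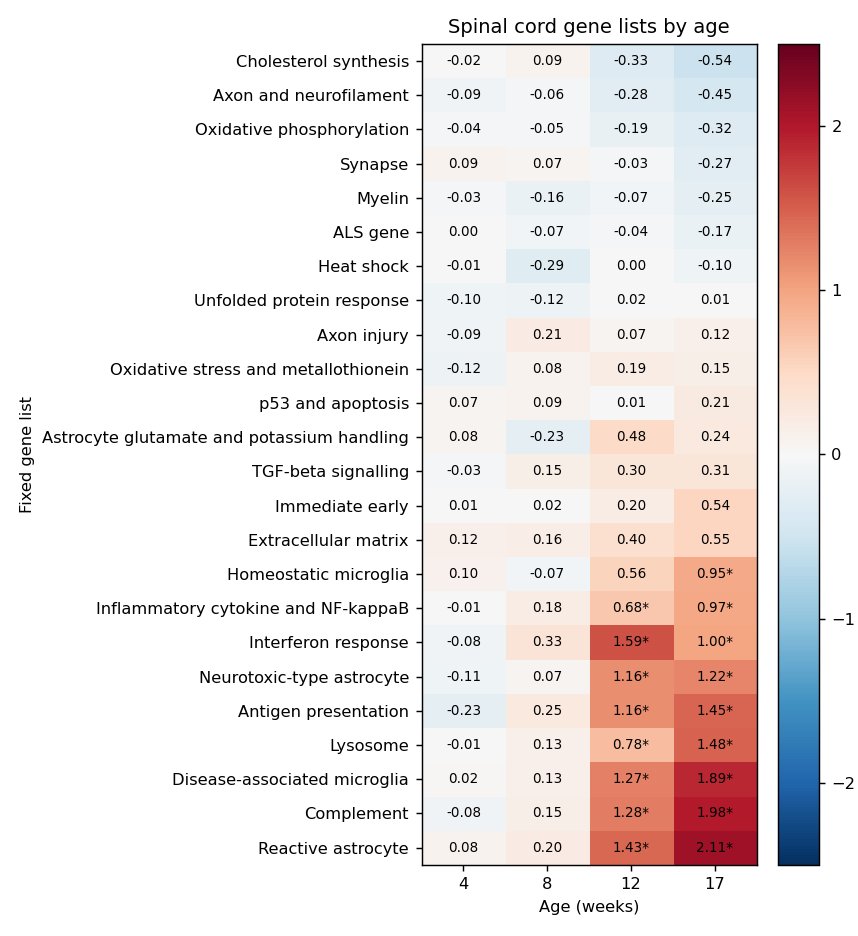
Median log2 fold change of mutant against wild-type spinal cord over the measured members of each gene list (colour), by age in weeks. A star marks an adjusted p under 0.05 with an estimated correlation, as for the reactive astrocyte list at 12 weeks (p = 0.00235) and 17 weeks (p = 0.00282).

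The 12-week and 17-week changes shared 214 of the 242 and 592 rising genes compared, where independence gives 9.88 (Fisher's exact test, 2-sided p = 2.84e-280), and 3 of 12 and 63 falling genes (p = 1.67e-05). Both ages stand in the same model, and Spearman's rho of the fold changes across genes was 0.45, genes not being independent replicates. Across the mean of all ages 535 genes passed (486 higher, 49 lower), among them Fmod, a collagen-binding proteoglycan, at 2.55-fold (log2 1.35, SE 0.09, adjusted p = 1.26e-07), S100a4 at 2.22-fold, Mpeg1 at 2.68-fold and the progenitor filament Nes at 1.78-fold. Chodl fell 1.70-fold (log2 -0.76, SE 0.10, adjusted p = 7.29e-05) and the tight junction gene Cldn5 1.36-fold (adjusted p = 0.029), which did not pass after rescaling (log2 -0.43 against -0.44, adjusted p = 0.068). After rescaling 1268 genes passed, 75.9% of them higher against 90.8%, and 1413 passed without the 17-week females.

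Whether the genotype effect differed with age was tested directly. The mutant effect was larger at 17 than at 4 weeks for Cst7 by 5.10 (SE 0.33, adjusted p = 4.03e-07), for Lyz2 by 4.65 (SE 0.37), for Serpina3n by 3.64 (SE 0.25, adjusted p = 4.37e-07) and for Gfap by 1.82 (SE 0.25, adjusted p = 0.000422) on the log2 scale, and lower for Chodl by -1.68 (SE 0.27, adjusted p = 0.00149). In all, 330 genes passed (316 higher, 14 lower), including 15 of 17 disease-associated microglia genes (adjusted p = 0.00229 with an estimated correlation), 11 of 14 microglia markers, 10 of 11 reactive astrocyte genes and 7 of 9 complement genes. Nefh differed by -0.81 (adjusted p = 0.3) and Nefm by -0.69 (adjusted p = 0.478). The count was 766 after rescaling and 654 with voom, and it was 199 without the male 17-week mutant and 203 without the male 4-week mutant.

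Wild-type spinal cord libraries differed between 17 and 4 weeks as well. Myelin genes were lower at 17 than at 4 weeks in 11 of 11 members (11 adjusted over the list alone; median log2 -1.57; adjusted p = 0.0725 with an estimated correlation). The myelin proteins Mal, Cldn11 and Mog fell 4.65-fold (SE 0.20, adjusted p = 1.95e-05), 3.99-fold and 3.21-fold, and Gpr17, a receptor of oligodendrocyte precursors, 4.95-fold (SE 0.23, adjusted p = 3.32e-05). All 10 oligodendrocyte markers (adjusted p = 0.0725) and all 16 cholesterol synthesis genes fell (adjusted p = 0.0858). The complement gene C4b rose 2.77-fold (adjusted p = 0.0155). Of 672 genes past the threshold 46 rose and 626 fell, and 17 of the 46 were small or ribosomal RNAs. The make-up of the libraries differed too. At 17 weeks the wild types held 21.6 M (female) and 32.4 M (male) reads on genes, of totals of 42.1 and 48.0 M. At 4 weeks they held 34.1 M (female) and 22.8 M (male), of totals of 43.2 and 29.5 M. Age and library make-up are thus not separated here. The median log2 change of all genes was -0.25, and rescaling moved it to 0.00 with 423 genes past the threshold, 19.9% of them higher against 6.85%. Relative to that shift Mal still fell 3.76-fold (SE 0.12, adjusted p = 7.91e-05) and Mog 2.60-fold, while Nefm, which fell by 0.88 (adjusted p = 0.0248), had -0.57 (adjusted p = 0.0872). The count was 144 without the female 17-week library and 2293 without the male.

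In cultured glia the question was what the mutant genotype of the glia themselves changed. With values as deposited, Aoc3 was the only gene past the threshold with wild-type neurons, at log2 -1.49 (SE 0.19, adjusted p = 0.00267), and with mutant neurons it was joined by 1 transcript listed at 0 in the wild-type glia, uc009gdm.1 (Aoc3 log2 -1.43, adjusted p = 0.0159). Mouse Sod1 had log2 changes of 0.33 (adjusted p = 1) and 1.02 (adjusted p = 0.907), and of 0.38 (SE 0.09, adjusted p = 0.0523) averaged over both partners in the blocked and rescaled model described next. A second model was fitted after these results were seen, with replicate number within each day as a block and median-of-ratios rescaling. That libraries with one replicate number varied together within a day was read only after its calls were known. The second model gave 36 genes with wild-type neurons (8 higher, 28 lower) and 24 with mutant neurons (4 higher, 20 lower). The median of all genes moved from 0.17 to 0.01 with mutant neurons, and the values that follow for glia and neurons come from that blocked model, except where the text says as deposited or unblocked.

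With wild-type neurons Aoc3 fell from 2.86 ± 0.259 to 0.362 ± 0.459 (SD, n = 6 each; log2 -1.56, SE 0.09, adjusted p = 1.08e-05), and with mutant neurons from 2.99 ± 0.283 (n = 5) to 0.336 ± 0.345 (n = 6; log2 -1.64, adjusted p = 1.87e-05). The secreted signal Wnt4 fell 2.03-fold (SE 0.11, adjusted p = 0.00414) and 1.74-fold (SE 0.12, adjusted p = 0.0276) with the 2 partners. Its log2 changes at days 3, 7 and 14 were -0.53, -2.14 and -0.38 with wild-type neurons and -0.61, -1.66 and -0.13 with mutant neurons. The cilia gene Cfap161 fell 1.54-fold and 1.47-fold. Cldn11 passed as a mean over days (log2 -0.71 and -0.64), but its log2 changes were 0.51, -0.61 and -2.04 at days 3, 7 and 14 with wild-type neurons and 0.43, -0.51 and -1.84 with mutant neurons. The GABA transporter Slc6a13 fell 1.92-fold with wild-type neurons, where the synaptic adhesion gene Slitrk5 rose 1.56-fold, Syndig1 1.45-fold and the growth factor Nrg1 1.28-fold. Slc6a13 (log2 -0.04, -2.65 and -0.14 at days 3, 7 and 14) and Slitrk5 (0.06, 1.63 and 0.22) changed mainly at day 7. Syndig1 rose on each day (0.255, 0.754 and 0.602). The Y-linked Eif2s3y rose 4.04-fold with wild-type neurons (SE 0.23, adjusted p = 0.00414), with log2 changes of 0.07, 5.18 and 0.79 at days 3, 7 and 14, so the sex make-up of the cultures differed between the genotypes. Among 13885 genes whose symbol labels 1 entry, 27 fell with wild-type neurons, 19 with mutant neurons and 14 with both. The overlap was not tested, since the contrasts stand in 1 model and the changes of Eif2s3y by day, alike with both partners, leave open that they share glial preparations.

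Averaged over both partners, 262 genes passed in mutant glia (37 higher, 225 lower), against 2 with values as deposited and no block. Interferon-induced genes fell in 10 of 13 members (12 adjusted over the list alone; median log2 -0.51; adjusted p = 0.266 with an estimated correlation), with Ifi27l2a at -0.75 (SE 0.10, adjusted p = 0.00403), Ifit1 at -0.57 (adjusted p = 0.0131), Oas1a at -0.53 and Ifit3 at -0.51 (SE 0.08, adjusted p = 0.008). The list's median was -0.172, -0.835 and -0.364 at days 3, 7 and 14 with wild-type neurons and 0.304, -0.957 and -0.725 with mutant neurons, so it lay above 0 at day 3 there. Microglia markers fell in 2 of 13 members (7 adjusted over the list alone; median log2 -0.24; adjusted p = 0.266 with an estimated correlation), with the growth factor receptor Csf1r at -0.32 (adjusted p = 0.0259) and C1qb at -0.33 (adjusted p = 0.0473). Of 15 cytokine genes 1 fell, Cxcl10 at -0.69 (adjusted p = 0.0333; 5 adjusted over the list alone; list adjusted p = 0.713 with an estimated correlation). The complement list had C1s1 up by 0.21 and C1qb down (adjusted p = 0.362), and the ependymal list 1 of 5 down (adjusted p = 0.309). The heat shock list had a median of 0.00, a mean of -0.06 and a test pointing up (adjusted p = 0.978 with an estimated correlation), while its 1 called member, Hspa8, fell 1.84-fold (SE 0.17, adjusted p = 0.0249). By day alone 5, 725 and 176 genes passed at days 3, 7 and 14, day 7 being also where Eif2s3y differed most.

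The glial effect was set against spinal cord by Spearman's rho across genes, which was -0.10 for glia with wild-type neurons against 17-week spinal cord (jackknife SE 0.11 over 12 libraries, -0.14 to -0.03 with each left out), genes not being independent replicates. In the blocked and rescaled fits 58 genes that fell in mutant glia (of 141 compared) were among 1180 that rose in mutant spinal cord, where independence gives 15.2 (Fisher's exact test, 2-sided p = 6.05e-21, 10951 genes). They included the leukocyte surface protein Cd52 (log2 -0.70 in glia, SE 0.13, against 3.73 in spinal cord, SE 0.31), Ifit3 (-0.51 against 1.64), Rtp4 (-0.58 against 1.33) and Ctsc (-0.43 against 1.39). Microglia markers were among them, such as Csf1r (-0.32 against 1.58) and C1qb (-0.33 against 3.02). The microglia marker list was lower in mutant glia (median log2 -0.24) and higher in mutant spinal cord at 17 weeks. The overlap may thus reflect the share of microglia in each, which was not tested. Genes that rose in both numbered 4 (2.69 by independence), and genes that fell in both numbered 2 (3.72 by independence). Fisher's test takes genes as independent, which they are not. For the genes called in mutant glia chance was not excluded where preparations are shared.

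**Figure D3:**
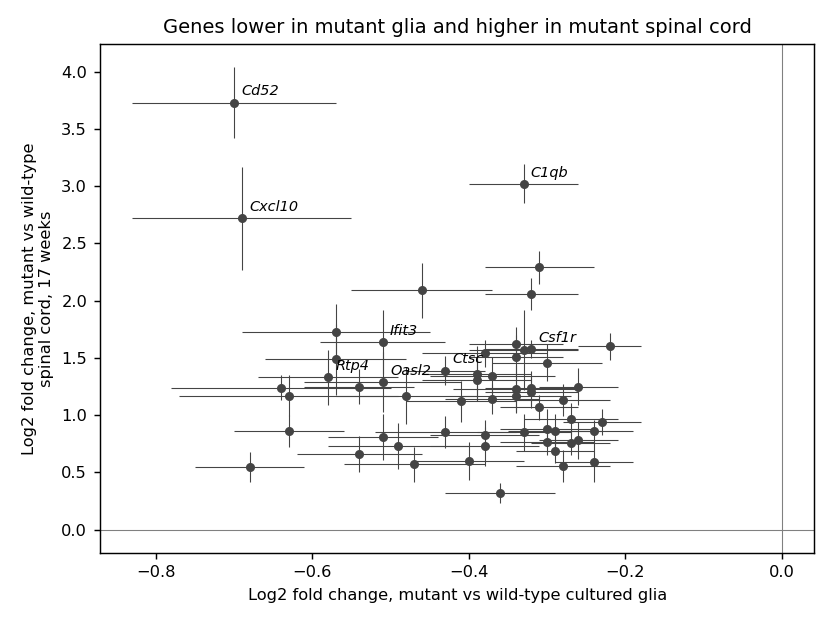
Log2 fold change in mutant glia (mean over both partners, x axis) and in mutant spinal cord at 17 weeks (y axis) for the 58 genes that fell in the first and rose in the second, with 1 point per gene and bars of 1 SE. Cd52 stands farthest, at -0.70 and 3.73.

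Whether mutant neurons changed the glia was asked next. Over wild-type glia 0 genes passed in limma (14 at an unadjusted p under 0.05, 204 in the blocked model, where 0 passed, while voom gave 0 and leaving out the filter on low values 5), and over mutant glia 1 passed, uc009gdm.1, which was listed at 0 in mutant glia with wild-type neurons and did not pass in the blocked model (0 genes, 159 at an unadjusted p under 0.05). Nefm, a neuronal filament, had a log2 change of -1.25 (adjusted p = 1) over mutant glia with values as deposited. Myelin genes had a positive test over wild-type glia (median log2 0.24; adjusted p = 0.866 with an estimated correlation). The test of whether the glial genotype effect depended on the neuron genotype gave 0 genes (11 at an unadjusted p under 0.05, 72 in the blocked model with 0 past the threshold, and 3 genes called without the filter on low values). These unadjusted counts lie below the share of 0.05 of genes that chance alone would give. At day 14 residuals correlated at 0.91 (mutant glia) and 0.87 (wild-type glia) between the 2 partners, against 0.23 to 0.34 between glia genotypes. Neither model used that pairing, so the tests may be too strict, and 0 genes do not show that neurons left the glia unchanged.

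Wild-type glia over wild-type neurons were compared between day 3 and day 14 with values as deposited, since a block within each day removes the spread between replicates that a comparison of days needs. No gene passed (limma, 0 genes, 1018 at an unadjusted p under 0.05), with a median log2 change of -0.31 over all genes, while 15 passed after rescaling and 9 with voom, both without a block. Immediate early genes had the strongest list test (median log2 0.62, 0 of 10 past the threshold; adjusted p = 0.243 with an estimated correlation), with Egr1 at 97.0 ± 3.41 against 41.7 ± 13.4 at day 3 (SD, n = 2 each; log2 1.23, SE 0.53, adjusted p = 0.677) and Fos at log2 1.20 (SE 0.42, adjusted p = 0.524). Myelin genes had a median of -1.22 (2 of 11 adjusted over the list alone; adjusted p = 0.751 with an estimated correlation), with Cldn11 at -2.19 (SE 0.54, adjusted p = 0.295). Mouse Sod1 had a change of -1.49 (SE 1.05, adjusted p = 0.809), and of 0.23 without day 3 replicate 1, where 1 gene passed.

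In neurons the question was what the mutant genotype of the neurons changed. Nxf3, an X-linked RNA export factor, was 5.81 ± 3.77 in mutant neurons with wild-type glia (SD, n = 3) against 0.0989 ± 0.123 in wild types (n = 5), a log2 change of 2.31 (SE 0.20, adjusted p = 0.00347). With mutant glia it rose by 2.47 (SE 0.15, adjusted p = 0.000162). The germ-cell genes Cyct and Trap1a rose 4.32-fold and 4.61-fold with mutant glia (SE 0.15 and 0.16), and Rec8, a meiotic cohesin, rose 2.74-fold with wild-type glia (SE 0.14, adjusted p = 0.00726). Aoc3 fell 2.41-fold (SE 0.14, adjusted p = 0.014) and 2.81-fold (SE 0.11, adjusted p = 0.000299), and Nefm fell 2.84-fold with mutant glia (SE 0.19, adjusted p = 0.00826), from 1486 ± 1686 to 389 ± 250 (n = 6 each). Mouse Sod1 had changes of 0.22 (adjusted p = 0.539) and 0.23 (adjusted p = 0.272).

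Most inhibitory interneuron markers were higher in mutant neurons. Slc32a1, the vesicular GABA transporter, rose 2.63-fold with wild-type glia (SE 0.19, adjusted p = 0.0289) and 2.15-fold with mutant glia (SE 0.14, adjusted p = 0.00776). Averaged over both glia, 5 of 7 members rose (6 adjusted over the list alone; median log2 0.76; adjusted p = 0.0728 with an estimated correlation), with the transcription factors Pax2 at 2.11-fold (SE 0.11, adjusted p = 0.00184) and Lhx1 at 1.71-fold (on chromosome 11, which was higher as a whole), the glycine transporter Slc6a5 at 1.69-fold and the GABA-synthesising Gad2 at log2 0.59. Astrocyte markers rose in 4 of 12 members, with Gfap, also on chromosome 11, at 3.04-fold (SE 0.23, adjusted p = 0.00482) and Aldh1l1 at 2.32-fold (5 adjusted over the list alone; adjusted p = 0.635 with an estimated correlation). Pluripotency markers rose in 3 of 6, with Dppa5a at 2.25-fold and Pou5f1 at 1.76-fold (5 adjusted over the list alone; adjusted p = 0.635). The rise lay mainly at day 7, with Dppa5a at -0.44, 3.46 and -0.02 at days 3, 7 and 14 with wild-type glia and 0.08, 3.69 and 0.26 with mutant glia, and Pou5f1 at 0.53, 2.39 and 0.17 with mutant glia. Pan-neuronal genes were 3 up and 1 down, with a median log2 of 0.03 and a mean of -0.00 (adjusted p = 0.896).

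Part of the matrix, interferon and stress lists was lower in the same mutant-neuron libraries. Extracellular matrix genes fell in 6 of 15 members, with the collagen-crosslinking Lox at 2.32-fold (SE 0.21, adjusted p = 0.00825) and Fn1 at 1.66-fold (7 adjusted over the list alone; adjusted p = 0.635 with an estimated correlation), and 3 of 8 fibroblast markers fell (6 adjusted over the list alone; adjusted p = 0.635). Interferon-induced genes fell in 5 of 13, with Ifit1 at 1.83-fold and Usp18 at 1.73-fold (7 adjusted over the list alone; median log2 -0.48; adjusted p = 0.635), though both were higher in the 1 mutant library at day 14 with wild-type glia. The unfolded protein response list had 4 of 12 down, with Atf4, a stress transcription factor, at 1.32-fold (SE 0.06, adjusted p = 0.00574) and Trib3 at 1.44-fold (7 adjusted over the list alone; adjusted p = 0.349). TGF-beta signalling had 3 of 16 down, with Tgfb3 at 1.61-fold (5 adjusted over the list alone; adjusted p = 0.635), antigen presentation 2 of 10, with B2m at 1.59-fold (6 adjusted over the list alone; adjusted p = 0.635), and muscle genes 2 of 4, with Actc1 at 1.84-fold (adjusted p = 0.493). Members of the fibroblast, muscle, astrocyte, interneuron and pluripotency lists all differed between the genotypes. The cell make-up of these libraries and changes within neurons are thus not separated, which was not tested.

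Genes on chromosome 11 were higher in mutant neurons. Averaged over both glia, the 951 genes of chromosome 11 with a mean value of at least 2 had a median log2 change of 0.37, or 1.29-fold, against -0.07 to -0.02 for the other chromosomes, and 94.6% of them were above 0 against 36.2% elsewhere. The medians with wild-type glia were 0.42, 0.36 and 0.40 at days 3, 7 and 14, and with mutant glia 0.33, 0.39 and 0.35. In mutant glia the medians of chromosome 11 were -0.02 to 0.05. Of 1286 called genes with a known chromosome 614 lay on chromosome 11 (607 higher, 7 lower), and of the others 271 were higher and 401 lower.

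**Figure D4:**
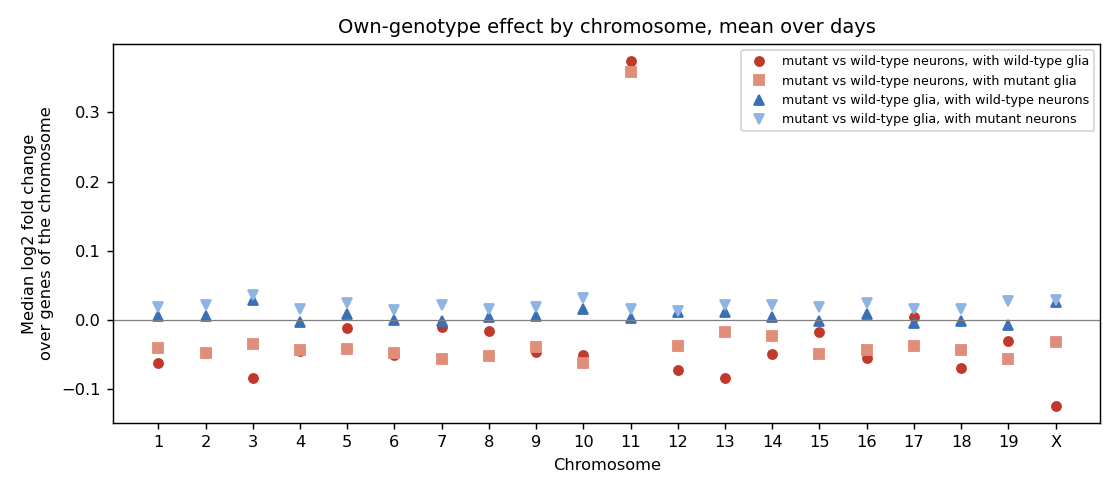
Median log2 fold change of mutant against wild-type libraries over the genes of each chromosome, in neurons (red) and glia (blue) with each partner, blocked and rescaled model. Chromosome 11 stands at 0.37 and 0.36 in neurons with wild-type and mutant glia, and at 0.00 and 0.02 in glia.

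With values as deposited the neuron genotype effect held 2 genes with wild-type glia (Nxf3 and the fall of uc008ckf.1) and 3 with mutant glia (Nxf3, Aoc3 and uc008ckf.1). The blocked model gave 23 (19 higher, 4 lower) and 734 (499 higher, 235 lower), and 1411 averaged over both glia (967 higher, 444 lower). Of the 19 genes that rose with wild-type glia 18 also rose with mutant glia, and all 4 that fell also fell, in contrasts that stand in 1 model. With mutant glia the unblocked count was 18 without the second day 3 library of mutant neurons and 6 without the second day 3 library of wild-type neurons.

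Whether mutant glia changed the neurons, the question of glial toxicity, was tested in both neuron genotypes. No gene passed under wild-type neurons (limma, 0 genes, 90 at an unadjusted p under 0.05, 477 in the blocked model) or mutant neurons (0 genes, 63 and 231), in either model or with voom, while 77 and 34 genes passed without the filter on low values. Interferon-induced genes had the strongest list test, with a median log2 of -0.66 over both neuron genotypes, 0 of 13 past the threshold over all genes and 13 of 13 adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Irf7, an interferon regulator, had -0.79 (SE 0.15, adjusted p = 0.571), and the chemokines Ccl7 and Ccl2 had -1.04 (SE 0.16, adjusted p = 0.336) and -0.89 (SE 0.17, adjusted p = 0.571). Myelin genes had a median of 0.44, 6 of 9 adjusted over the list alone (adjusted p = 0.214), with Mbp at 0.69 (adjusted p = 0.999), and microglia markers a median of -0.21 (2 of 13 adjusted over the list alone; adjusted p = 0.645). The interferon list was lower in mutant glia themselves (median log2 -0.51), and the neuron libraries held glial transcripts such as Csf1r and Apoe. Glial RNA in the neuron libraries may thus give the changes of these lists, which was not tested. Sod1 had 0.11 (adjusted p = 0.999). The test of whether the neuron genotype effect depended on the glia gave 0 genes (24 at an unadjusted p under 0.05, 381 in the blocked model with 0 past the threshold, and 30 genes called without the filter). All these unadjusted counts lie below the share of 0.05 of genes that chance alone would give. The tests may thus be too strict, and 0 genes do not show that mutant glia left the neurons unchanged.

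Wild-type neurons over wild-type glia were compared between day 3 (n = 1) and day 14 (n = 2) with values as deposited and no block. The only day 3 library is one of the replicate 1 libraries with larger summed values, so day and that difference cannot be fully separated, and the spread of a lone library was assumed to be that of the other groups. The motor neuron transcription factors Mnx1 and Isl1 were 34.3-fold (SE 0.65, adjusted p = 0.00134) and 21.1-fold lower at day 14 (SE 0.48, adjusted p = 0.00121), the acetylcholine transporter Slc18a3 12.1-fold (SE 0.56) and the growth cone gene Gap43 20.7-fold (SE 0.79). The antioxidant Sod3 was 72.7-fold higher (SE 0.86, adjusted p = 0.00144), at 129 ± 81.9 (SD) against 0.606, and the astrocyte gene Aqp4 9.76-fold (SE 0.73, adjusted p = 0.0111), the 1 called member of 12 astrocyte markers (adjusted p = 0.749 with an estimated correlation). After rescaling without a block these genes had log2 changes of -4.39 (Mnx1), -3.72 (Isl1), -2.88 (Slc18a3), -3.64 (Gap43), 6.50 (Sod3) and 3.81 (Aqp4). Motor neuron genes were lower in 8 of 10 members, pan-neuronal genes in 11 of 12 and axon genes in 9 of 11 (adjusted p = 0.749 each with an estimated correlation). Sod1 had a change of -2.07 (SE 0.95, adjusted p = 0.131). In all, 2807 genes passed, 13.7% of them higher, with a median log2 change of -0.63 over all genes, and rescaling gave 3624, 52.6% of them higher. The count was 620 and 1204 without the first and the second day 14 library.

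The libraries of wild-type neurons and glia were compared to see what each held. Hoxa5, a spinal patterning gene, was 84.6 ± 29.7 in neuron libraries (SD, n = 5) and 0.533 ± 0.386 in glia (n = 6), 55.6-fold higher (SE 0.23, adjusted p = 6.84e-16). Nefm was higher 70.4-fold (SE 0.49, adjusted p = 1.34e-10), Snap25, a synaptic fusion protein, 39.2-fold (SE 0.27), Slc18a3 29.8-fold and Mnx1 23.2-fold. All 12 pan-neuronal, 10 motor neuron, 16 synapse and 11 axon genes were higher in neurons (pan-neuronal and motor neuron adjusted p = 0.0961 with an estimated correlation). All 12 astrocyte markers were higher in glia (adjusted p = 0.168), with Gfap at 206 ± 130 against 11.5 ± 10.5 (log2 -4.30, SE 0.43, adjusted p = 6.95e-09). Of 13 microglia markers 12 were higher in glia (13 adjusted over the list alone; adjusted p = 0.28), with Tmem119 8.12-fold and Csf1r 4.16-fold lower in neurons, where Csf1r still held 27.3 ± 28.3. Apoe, a lipid carrier, was 983 ± 693 in neuron libraries and 6172 ± 2364 in glia. With values as deposited, on which this paragraph rests, 6619 genes passed, of which 3861 were higher and 2758 lower in neurons, with 3678 past the threshold without the 1 day 3 library of wild-type neurons, and 10288 in the blocked model.

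Aoc3 lies on chromosome 11 at 101191919 to 101203253 (mm9). Its 8 mutant spinal cord libraries held 0 to 0.0669, and 7 of the 8 wild-type libraries lay higher, up to 3.34, while the 12-week wild-type female held 0.0221. In mutant and wild-type glia it held 0.0508 to 2.20 and 2.41 to 3.88, and in mutant and wild-type neurons 0.0439 to 1.10 and 1.67 to 3.63. The mutant glial values of 2.08 and 2.20 were both of day 3 replicate 1.

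**Figure D5:**
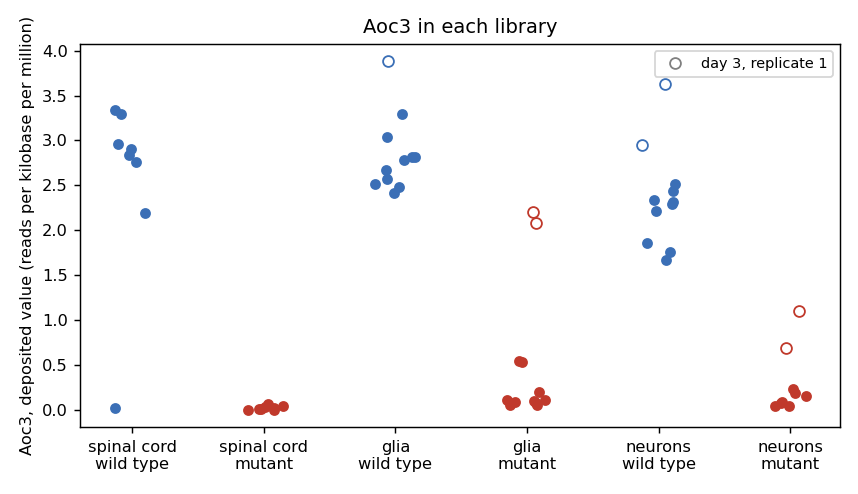
Deposited value of Aoc3 (RPKM in cultures) in each spinal cord, glial and neuronal library by genotype, with 1 point per library and open circles for day 3 replicate 1. The mutant spinal cord libraries lie between 0 and 0.0669, and 1 wild-type library, at 0.0221, lies among them.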

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

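The tests of chromosome 11, of Aoc3, of the interferon genes and of other splits of the libraries, and the genotype-by-day and genotype-by-sex tests, were chosen after the results were seen, while the genotype-by-age test was planned.

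In 2 places the mutant effect differed between groups by a test of the difference itself. In spinal cord it differed between 17 and 4 weeks for 330 genes (316 higher, 14 lower). In glia, averaged over both partners in the blocked and rescaled model, it differed between days for 292 of 14279 genes (2289 at an unadjusted p under 0.05), with 5, 725 and 176 genes called at days 3, 7 and 14 alone. The Y-linked Eif2s3y differed by log2 0.07, 5.18 and 0.79 on these days with wild-type neurons and by -0.29, 4.85 and 1.00 with mutant neurons, so a difference between glial preparations and an effect of day are not separated. In neurons the same test gave 0 genes (limma, 1531 at an unadjusted p under 0.05), with 129, 359 and 155 called by day. The spinal cord effect differed between the sexes for 0 genes (limma, 235 at an unadjusted p under 0.05, and 472 with 0 past the threshold after rescaling). Both unadjusted counts lie below the share of 0.05 of genes that chance alone would give, so the test between the sexes may be too strict.

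Each comparison of groups of at least 3 libraries was refitted with other splits of the same libraries within day, or within age and sex. Chance can be excluded for the mean of ages in spinal cord (535 genes, 4 of 100 splits as large, highest other 571), where the highest split exchanged the genotypes at 4 weeks alone. It can be excluded for neurons against glia (6619 genes, 1 of 100, highest other 5014). For glia with mutant neurons 2 of 100 splits were as large without a block, at a count of only 2 genes (highest other 5). In the blocked model, which follows the pairing of the libraries, 3 of 32 were (24 genes, highest other 54), so chance is not excluded there. It cannot be excluded for glia with wild-type neurons (1 gene, 7 of 100, highest other 23) or for neurons with mutant glia (3 genes, 34 of 100, highest other 5873). The same holds for mutant neurons over mutant glia (1 gene, 28 of 100, highest other 7443). Where the real count is 0 every split is as large by construction, so the splits decide nothing: mutant neurons over wild-type glia (100 of 100, highest other 58), mutant glia under wild-type neurons (100 of 100, highest other 98) and mutant neurons (27 of 27, highest other 1), and the interactions in glia (100 of 100, highest other 10229) and neurons (100 of 100, highest other 478). For neurons with wild-type glia (2 genes, 1 of 18, highest other 1) the splits are too few.

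The splits with 5873, 7443 and 58 genes separate the libraries by replicate number within days, and calls of this size, far above the real counts, point to a structure of the samples shared by libraries of a day with 1 number. With replicate number within each day as a block, and rescaling, the same comparisons gave 734, 0 and 0 genes. In that model chance can be excluded for neurons with mutant glia (734 genes, 1 of 32 splits, highest other 3) and for neurons against glia (10288 genes, 1 of 32, highest other 8702). For neurons averaged over both glia the splits gave 1 of 100 (1411 genes, highest other 191), and for glia averaged over both partners 3 of 100 (262 genes, highest other 1185). Both sets of splits take pairs with either partner as independent. Eif2s3y in glia and Dppa5a in neurons changed alike by day with both partners, so chance is not excluded where preparations are shared. The split with 1185 genes exchanged 7 of 11 pairs, including all but 1 of the pairs with wild-type neurons, so a structure other than genotype remains among the glial libraries. Chance cannot be excluded for glia with wild-type neurons (36 genes, 5 of 32, highest other 49) or, as said, with mutant neurons, and for neurons with wild-type glia (23 genes, 1 of 8, highest other 0) the splits are too few.

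Genes of chromosome 11 were higher in mutant neurons, with a median log2 change of 0.37 (951 genes), and of 0.37 over the 613 genes with a mean of at least 10, of which 95.8% were above 0. The scaling of the libraries is argued against, as no other chromosome had a median above -0.023 with values as deposited. So are a single region, as 13 of 13 stretches of 10 megabases lay above every other chromosome (0.336 to 0.399), and glial RNA, as genes higher in neurons than in glia had a median of 0.414. An extra copy of chromosome 11 in part or all of the mutant neurons may explain it, since the lowest of the 6 day and partner medians was 0.334, but no DNA was read, and the origin of the neuron lines and the genotype cannot be separated here.

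Aoc3 was lower in mutants in spinal cord, glia and neurons. A mutant library labelled wild type is argued against for the 12-week wild-type female, which lay at -0.006 between the other wild types (0) and the 12-week mutants (1) over 313 genes that rose at 17 weeks. Of 52 neighbours within 1 megabase 4 were called, with a median log2 change of -0.01. An effect of the mutant genotype itself stays open, as 1 of 8 wild-type spinal cord libraries lay in the mutant range. A variant carried by the strain or donors of the mutant line may also explain it, given 0.0221 in that wild-type female. The 2 cannot be told apart, because no DNA was read and such a variant would go with the mutant line.

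Interferon-induced genes were lower in mutant glia, with a median log2 change of -0.51 and 13 of 13 members below 0. Fewer microglia among the mutant glia are not settled. With the mean of the microglia markers as a term the median was -0.587 and did not move towards 0 (the markers' own median being -0.24). But the markers' median had the sign of the list's median in all 6 day and partner contrasts. It was -0.034, -0.367 and -0.301 at days 3, 7 and 14 with wild-type neurons, and 0.182, -0.314 and -0.356 with mutant neurons. A lower share of microglia may thus contribute to the fall. Other glial preparations on some days may explain it: where Eif2s3y differed by less than 1 log2 the mean of the contrasts' medians was -0.077 over 3 contrasts, 1 of them positive (0.304), and with a bound of 2 it was -0.239 over 4, so the answer depends on the bound and on that contrast. A lower response set by the mutant genotype stays open, with 5 of the 6 day and partner contrasts below 0. Genotype and preparation cannot be told apart because mutant and wild-type glia of a day differ in both. The medians at days 3, 7 and 14 were -0.172, -0.835 and -0.364 with wild-type neurons and 0.304, -0.957 and -0.725 with mutant neurons.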

How the results depend on the processing

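Chosen after the data were seen were the replicate block within each day, its combination with rescaling, voom on recovered reads, the models without the day 3 replicate 1 libraries or the 17-week females, and the contrasts averaged over both partners. Over the named genes, the alternatives set beforehand left 3282 values with their direction and side of the threshold, while 173 became stronger, 256 weaker and 3 reversed. The added alternatives gave 2518, 1089, 166 and 14, and leaving out single libraries 5826, 52, 670 and 21. Where a count or direction changed below, the cause was not tested, except that a block within each day takes the spread between replicates out of a comparison of days, so blocked counts of day 14 against 3 do not test day.

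In spinal cord, counts after median-of-ratios rescaling were 0, 13, 458 and 1784 at 4, 8, 12 and 17 weeks, 1268 over all ages, 766 for genotype by age and 423 for wild-type ageing (13, 35, 256, 661, 535, 330 and 672 as deposited). Voom gave 0, 95, 650, 1612, 1424 and 654 for the first 6. No filter gave 3 at 4 weeks, 1 at 8 weeks and 381 for ageing. At 8 weeks a pseudocount of 0.1 gave 21 and no sex term 16. Without the 17-week females the mean of ages gave 1413 and ageing 365. Leaving out 1 library gave 8 (wild-type replicate 2) to 126 (wild-type replicate 1) at 4 weeks, 2 to 25 (the same 2) at 8 weeks, and 102 (wild-type replicate 2) to 238 (mutant replicate 2) at 12 weeks, with 137 without mutant replicate 1. It gave 572 to 915 at 17 weeks, 370 to 708 for the mean, and 199 (17-week mutant replicate 2) to 385 (17-week mutant replicate 1) for genotype by age, with 203 without 4-week mutant replicate 2. Ageing ran from 144 (17-week wild-type replicate 1) to 2293 (17-week wild-type replicate 2). A group left with 1 library was assumed to vary like the others.

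For glia with wild-type neurons (1 as deposited) rescaling gave 4, no filter 2, the replicate block 2, the block within each day 22 and 36 with rescaling, and voom 2 and 35 with that block. With mutant neurons (2) no filter gave 9, a pseudocount of 0.1 and the additive model 1 each, the block within each day 11 and 24 with rescaling, voom with the block 37, and 1 remained without day 3 replicate 1. Averaged over partners (2) rescaling gave 15, no filter 8, a pseudocount of 0.1 7, the replicate block 6, the block within each day 133 and 262 with rescaling, voom 23 and 409 with the block, and 4 came without day 3 replicate 1. The neuron genotype over wild-type glia (0) gave 5 with no filter, as did 3 for the averaged partner effect and 3 for the interaction. Over mutant glia (1) the count was 0 with rescaling, no filter, a pseudocount of 0.1, the additive model, the block within each day with and without rescaling, voom with and without the block, and without day 3 replicate 1. Day 14 against 3 (0) gave 15 with rescaling, 42 with the replicate block, 3936 and 1565 with the block within each day without and with rescaling, voom 9 and 1371 with the block, and 1 without day 3 replicate 1.

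For neurons with wild-type glia (2) rescaling gave 4, no filter 103, the additive model 4, the block within each day 23 with and without rescaling, voom 0 and 23 with the block, and 4 came without day 3 replicate 1. With mutant glia (3) rescaling gave 19, no filter 8, the additive model 8, the block within each day 706 and 734 with rescaling, voom 12 and 752 with the block, and 9 came without day 3 replicate 1. Averaged over glia (12) the counts were 385 with rescaling, 84 with no filter, 30 with the replicate block, 1431 and 1411 with the block within each day without and with rescaling, voom 237 and 1303 with the block, and 54 without day 3 replicate 1. The glial genotype (0) gave 77 under wild-type neurons, 34 under mutant neurons and 43 averaged with no filter, 1 under mutant neurons without day 3 replicate 1, and the interaction 30 with no filter. Day 14 against 3 (2807) gave 7245, 6399 and 5739 with the block, the block with rescaling and voom with the block, and neurons against glia (6619) gave 10258, 10288 and 10206. List tests that passed fell from 235 to 37 with an estimated correlation.

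In cultures the counts with each library left out were 0 to 3 for glia with mutant neurons (3 without wild-type glia with mutant neurons at day 3), 0 to 1 for mutant neurons over mutant glia, and 0 to 170 for glial days (170 without day 3 replicate 2). They were 2 to 18 for neurons with mutant glia (18 without day 3 replicate 2 of mutant neurons, 6 without that of wild-type neurons), 620 to 1204 for neuronal days (without day 14 replicate 1 and 2), and 3678 (without day 3 of wild-type neurons) to 6323 for neurons against glia. Spearman's rho of glia against spinal cord ran from -0.114 to -0.02 across alternatives and from -0.14 to -0.03 with each library left out.

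Directions reversed for few genes. In glia between days 14 and 3, Dppa5a (-0.87) had 0.17 with voom, and without day 3 replicate 1 Sod1 (-1.49) had 0.23 and Dync1h1 (0.06) -0.02. In neurons between days, Fbln1 had 0.19 with rescaling, 0.48 and 0.71 with the block within each day without and with rescaling, 0.21 with voom and 0.81 with voom and the block. Cdk1 (-0.02) had 0.65, 1.11, 1.37, 0.71 and 1.59 in the same order, and 0.46 with the replicate block. In neurons averaged over glia Cx3cr1 had 0.08 with a pseudocount of 0.1, 0.19 with voom and 0.14 without day 3 replicate 1. With single libraries left out, Slc1a2 in 17-week spinal cord ran from -0.03 to 0.62, Cfap161 in glia with mutant neurons from -0.58 to 0.18, and Sod1 between neurons and glia from -0.87 to 0.28. In glia between days the ranges were -3.21 to 0.23 (Sod1), -1.88 to 0.13 (Dppa5a), -0.13 to 0.65 (Fas), -0.14 to 0.66 (Trp53inp1), -0.03 to 0.25 (Jun), -0.02 to 0.15 (Dync1h1) and -0.16 to 0.22 (Fig4). In neurons between days they were -3.11 to 0.13 (Cx3cr1), -0.01 to 0.71 (Fabp7), 0 to 1.07 (Lgals3), -0.15 to 0.74 (H2-K1), -0.33 to 0.28 (Cdk1), -0.04 to 0.32 (Aurkb) and 0 to 1.13 (Egr1).

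In libraries simulated from the rescaled values, log2 changes of 1 were found in 84% of genes for spinal cord at 17 weeks, 79% for glia with wild-type neurons and 70% for neurons with mutant glia, so part of the changes of that size would be missed. The simulation left out the scaling differences of the deposited values, so the unblocked culture models may miss more than these rates say. Since the changed genes were drawn above a minimum mean value, more may also be missed among genes with lower values.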

Other observations

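The blocked and rescaled model used in part here was chosen only after the results were seen, and no explanation was tested. In spinal cord at 17 weeks, the progenitor genes Nes and Fabp7 rose 3.03-fold (SE 0.23, adjusted p = 0.000219) and 1.95-fold (SE 0.20, adjusted p = 0.00526), 2 of 5 neural progenitor markers (2 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation). Immediate early genes were 2 up and 1 down of 7 (5 and 1 adjusted over the list alone; adjusted p = 0.0898), with Junb at 2.16-fold (SE 0.18), Fos at 1.70-fold and Arc down 1.51-fold. The death receptor Fas rose 1.93-fold (SE 0.20, adjusted p = 0.006), the 1 called member of 11 p53 and apoptosis genes (adjusted p = 0.312).

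In wild-type neurons between days 3 (n = 1, a replicate 1 library with larger summed values) and 14 (n = 2) of culture, with values as deposited and no block, Ecrg4, a secreted peptide precursor, was 27.1-fold higher at day 14 (SE 0.98, adjusted p = 0.00749). The migrating-neuron gene Dcx was 22.5-fold lower (SE 0.48, adjusted p = 0.00121). Cholesterol synthesis genes were lower in 9 of 15 members (12 adjusted over the list alone; adjusted p = 0.749 with an estimated correlation), with Fdps 5.70-fold lower (SE 0.43, adjusted p = 0.0034).

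Reactive astrocyte and complement genes, like the astrocyte and microglia markers, were higher in wild-type glia than in neurons. Lcn2, an iron-binding protein of reactive astrocytes, was 28.4-fold lower in neurons (n = 5) than in glia (n = 6; log2 -4.83, SE 0.36, adjusted p = 2.67e-11), and all 13 reactive astrocyte genes (adjusted p = 0.0961 with an estimated correlation) and all 11 complement genes (adjusted p = 0.167) were lower in neurons, with C3 11.9-fold lower (SE 0.49, adjusted p = 1.63e-06). The cell cycle gene Ccna2 was 3.44-fold higher in neurons (SE 0.37, adjusted p = 0.000313).

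In mutant neurons averaged over both glia (blocked and rescaled model), the imprinted RNA Meg3 rose 2.96-fold (SE 0.16, adjusted p = 0.00179) and the hormone precursor Pomc 2.62-fold (SE 0.14, adjusted p = 0.00179). In mutant glia averaged over both partners, the glutamate receptor gene Gria1 fell by 0.59 on the log2 scale (SE 0.13, adjusted p = 0.0424).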
